A study of Mus musculus with 39 samples.

How the data were processed

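The series holds 39 RNA sequencing libraries of astrocytes from male mice that went through chronic social defeat stress or served as controls. In this procedure a mouse is repeatedly exposed to an aggressor and is later classed as susceptible or resilient by its social behaviour. Per the labels' protocols, cells were taken from freshly punched nucleus accumbens tissue (NAc) with magnetic beads against ACSA-2, an astrocyte surface epitope on the ATPase subunit encoded by Atp1b2. The protocol names NAc tissue for every library, while the tissue label of 17 libraries reads PFC, an abbreviation that the labels do not spell out and that is read here as prefrontal cortex. Per the labels' protocols, total RNA was extracted with a Zymo column kit, and 500 pg went into Takara's SMARTer Stranded Total RNA kit for picogram input, which does not select polyadenylated RNA. Each of the 39 libraries carries its own mouse number, which equals its sample number. Odd sample numbers are PFC and even ones NAc, and the 16 pairs of consecutive numbers each share their condition. NAc and PFC libraries of such a pair may therefore come from the same mouse, which the labels do not settle. The main fits treated all libraries as separate mice.

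The deposited counts are whole numbers per gene for 55401 genes, made by the authors with featureCounts on the mm10 build per the submitters' processing notes. The versions, the aligner, the annotation and the strand setting are not given in the sources used here. The deposited FPKM are the same counts divided by gene length and by the library total. The length implied by counts and FPKM equalled the whole gene span, introns included, in GENCODE release M21 within a relative difference of 1e-06 for 54229 of 54229 genes compared, so the counts cover introns as well as exons. The genes compared were those whose identifier matched the release with its version and that had a count in any library. Of the gene identifiers, 55141 matched that release without their version and 260 had no name there. Coordinates below are those of GENCODE M21 on mm10. No 2 libraries held identical counts.

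Because counts cover whole gene bodies, a background cover was measured in each library from 1479 genes of the olfactory, vomeronasal and trace-amine receptor families, most of which are silent outside sensory tissue. Their FPKM, summed counts over summed gene spans, was divided by 0.764, the FPKM that every gene would have if a library's counts lay evenly over the 1308.8 Mb of summed gene spans, and given as a percent. This measure was devised after the data were examined.

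Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with trimmed-mean scaling, the default count filter by group, robust dispersion and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. The 3 conditions of a region were fitted together, which tested 35943 genes in NAc and 32167 in PFC. The comparison of regions in controls and the difference of each stress effect between regions came from 1 fit of all 39 libraries in 6 groups, with 38171 genes. No block entered these fits. The test never returns a p below that of a Poisson likelihood-ratio test, which raised the p of 1765, 1566 and 1506 genes in the NAc comparisons of susceptible with control, resilient with control and susceptible with resilient mice, of 472, 567 and 571 genes in the same PFC comparisons, and of 1192, 1278 and 1455 in the region comparison and the susceptible and resilient interactions. Without that bound the counts of called genes were the same. Fold changes are on the log2 scale with their standard error, CPM values use the scaling of the fit they belong to, and values per group are mean ± SD. All p-values measure the spread between libraries as labelled and are two-sided. If no gene changed, about 1797 genes per NAc comparison and 1608 per PFC comparison would have an unadjusted p under 0.05. In the fit of all libraries it would be about 1909 per comparison.

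On simulated counts with 200 changed genes of log2 CPM above 3, the test recovered 46.3% of 1.5-fold, 94.0% of 2-fold and 100% of 4-fold changes for NAc susceptible against control mice, with 6 false calls among 171. For PFC susceptible against control mice it recovered 1.49%, 22.4% and 93.9%, with 4 false calls among 83, and for the regions in controls 16.4%, 67.2% and 98.5%, with 4 false calls among 125. A further 20 genes shifted by 0.5 log2 could be among the calls and were counted neither as recovered nor as false. The simulation drew genes independently, without structure shared between libraries and without background diluting the changes. These figures may therefore overstate recovery and the control of false calls in the real libraries.

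Before the data were examined, 40 gene lists of cell types, astrocyte states, signalling and metabolism were fixed and tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, with at least 5 measured members. Camera with an estimated correlation and fry were run beside it. The lists described in detail were picked after these results were seen. Camera sets a list against all genes tested, while only 10612 genes in NAc, 12256 in PFC and 12771 over all libraries lay above background as defined below. A shift shared by expressed genes can therefore make many lists pass in the same direction. The mean log2 CPM of each of 13 cell type lists was also compared between groups with exact permutation tests, and in PFC also within same-numbered pairs by changing the signs of the differences, which was chosen after the data were examined. In the 7 comparisons of 2 groups, genes were named by a rule fixed before the data were examined. Among genes with an average log2 CPM above 1 and a symbol that is neither predicted, clone-based nor a pseudogene's, it takes in each direction the 5 largest fold changes past the threshold and the 5 smallest p-values not already taken, and where fewer than 10 pass it fills the places by the smallest unadjusted p, given as not passing. It also takes up to 4 members of each list described by smallest p, the genes Creb1, Crem and Atf1 in each NAc comparison, and the levels of Atp1b2, Aldh1l1, Aqp4 and Slc1a3. For each interaction it takes the 5 smallest p. Some genes that this rule takes are not reported here. Genes of the olfactory, vomeronasal, haemoglobin and H2 families share reads with near-identical copies, and antisense genes cannot be told from their partners without the strand setting, so both kinds are uncertain.

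The alternatives fixed before the data were examined were relative log expression scaling, no count filter, a stricter count filter, DESeq2 1.42.0, limma-voom with library weights, limma-trend on log2(FPKM + 0.5), the replicate number as a block, 2 surrogate variables from sva 3.50.0, 2 principal components of cell type markers, the sample number as a covariate, fits of only the 2 groups or of all libraries, and each library left out in turn. Also fixed before were consecutive sample numbers as pairs between the regions and a count at an unadjusted p under 0.05 with a fold above 1.3. Those chosen after the data were examined were the background percent as a covariate, only genes with a mean FPKM at least 2 times the mean background FPKM of the receptor genes, both together, and the data without the 3 libraries with the lowest totals. For the region comparison, leaving out control replicates 1 and 2 of both regions was chosen after as well.

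The replicate numbers are those in the library names of the labels, and no label ties them to litters, cages or days. Deviations from the group means of same-numbered PFC libraries correlated over 0.1 for every pair among genes of log2 CPM above 3, the level looked at first, with lowest values of 0.409, 0.154 and 0.214 for control with resilient, control with susceptible and susceptible with resilient libraries. Among genes of log2 CPM above 1 this held for 5 of 5, 5 of 6 and 4 of 5 pairs, with lowest values of 0.216, 0.0315 and 0.0640. PFC was therefore treated as paired by number when splits were compared, and NAc was not, since its same-numbered libraries correlated with both signs. In the same order of PFC groups, however, only 1 of 5, 2 of 6 and 2 of 5 libraries correlated best with their own number. The replicate numbers rise with the sample numbers within each group, so a match by number can also reflect nearness in that order. A true pairing of PFC libraries is therefore not established. Same-numbered NAc resilient libraries also correlated over 0.1 with PFC control, susceptible and resilient libraries, in 6 of 6, 5 of 6 and 4 of 5 pairs among genes of log2 CPM above 1. The fits and splits of the interactions and the relabellings of the correlation between regions did not take this match into account.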

Results

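Gene expression was measured in 39 libraries of ACSA-2-sorted astrocytes of male mice, each with its own mouse number, in 2 regions and 3 conditions. NAc contributed 7 control, 8 susceptible and 7 resilient libraries, and PFC contributed 6 control, 6 susceptible and 5 resilient libraries. The title of the series names the transcription factor CREB in astrocytes of the NAc as a promoter of stress susceptibility, and its design text states the aim of describing how the NAc astrocyte transcriptome responds to chronic social defeat. Counts assigned to genes ranged from 0.941 to 37.3 M (mega, counts per library) with a median of 11.3 M. Group means were 12.4 ± 7.63, 13.9 ± 6.26 and 15.8 ± 12.1 M in NAc control, susceptible and resilient mice (SD; n = 7, 8 and 7). In PFC they were 15.2 ± 7.97, 9.22 ± 6.47 and 8.30 ± 7.12 M (n = 6, 6 and 5). The shallowest libraries were NAc control replicate 3 with 0.941 M, PFC susceptible replicate 6 with 1.22 M and PFC resilient replicate 3 with 1.60 M.

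Astrocyte transcripts were abundant in all 6 groups. Atp1b2, which encodes the sorted epitope, stood at 253 ± 96.2, 223 ± 70.2 and 171 ± 118 CPM of the library total in NAc control, susceptible and resilient mice (SD; n = 7, 8 and 7). In PFC it stood at 240 ± 106, 382 ± 218 and 399.6 ± 293 CPM (n = 6, 6 and 5). The glutamate transporter Slc1a3 stood at 884 ± 308, 822 ± 335 and 617 ± 425 CPM in NAc and at 680 ± 282, 1079 ± 581 and 1020 ± 793 CPM in PFC. Aldh1l1, a folate enzyme used as an astrocyte marker, lay at 141, 144 and 122 CPM in NAc and 115, 150 and 135 CPM in PFC. The water channel Aqp4 lay at 118, 99.7 and 69.3 CPM in NAc and 110, 170 and 160 CPM in PFC. Transcripts of other cells were present as well. The myelin gene Mbp was at 644 ± 263, 425 ± 178 and 331 ± 157 CPM in NAc, and the microglial receptor Cx3cr1 at 90.6 ± 18.7, 105 ± 14.4 and 103 ± 20.7 CPM in the same groups. Chemosensory receptor genes carried a cover that ranged from 13.4% to 81.1% of the level at which all counts would lie evenly over the genes, with a median of 58.2%. This background averaged 53.2 ± 9.25%, 56.0 ± 7.95% and 64.55 ± 10.5% in NAc control, susceptible and resilient mice and 50.5 ± 17.8%, 46.8 ± 18.1% and 47.3 ± 23.8% in PFC. The cover was not the same in all genes held to be silent. In 60 single-copy genes of other organs the median FPKM was 0.616, against 0.400 in the receptor genes. The receptor genes may therefore understate the background.

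**Figure D1:**
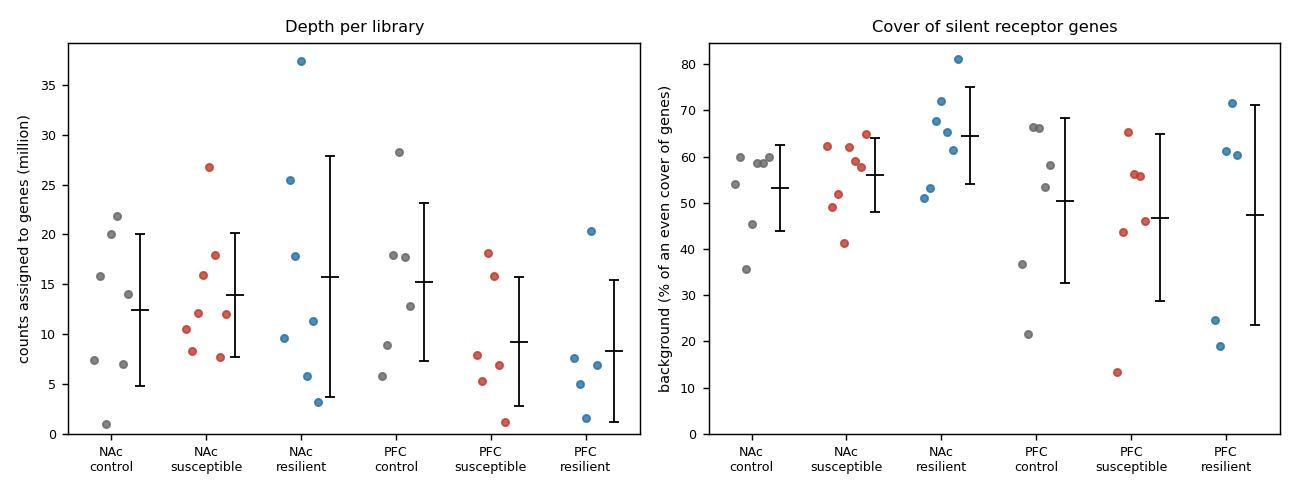
Total counts assigned to genes (M, mega) and the background percent (cover of chemosensory receptor genes relative to an even cover) in each library of the 6 groups; points are libraries and bars mean ± SD. Totals run from 0.941 to 37.3 M and the background from 13.4% to 81.1%.

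Susceptible and control mice in the NAc address how astrocytes differ in mice that develop social avoidance. Creb1, which encodes CREB (ENSMUSG00000025958.14, mm10 chromosome 1, 64532645 to 64604548), stood at 51.7 ± 9.09 CPM in 8 susceptible and 62.7 ± 17.1 CPM in 7 control libraries, a log2 fold change of -0.26 ± 0.15 (SE) that did not pass. Crem and Atf1, the other members of its family, had log2 fold changes of -0.04 ± 0.12 and -0.04 ± 0.10, and both turned positive under some alternatives, such as 0.03 and 0.05 with marker components of other cell types. Counts cover whole gene spans, so part of the CPM of Creb1, Crem and Atf1 is background, which was not subtracted. For a span as long as that of Creb1 this part may be large. Receptor genes averaged 0.442 FPKM over the 22 NAc libraries. A change of the transcripts themselves may therefore appear smaller than it is, and the lack of a call for Creb1 does not exclude such a change. Among abundant genes, the calcineurin regulator Rcan2 (chromosome 17, 43801351 to 44039516) was at 236 ± 22.6 against 300.5 ± 48.7 CPM, and the lipoprotein and reelin receptor Vldlr (chromosome 19, 27216484 to 27254231) at 31.6 ± 5.44 against 45.8 ± 15.7 CPM. Higher values were seen for the channel gene Panx2 (chromosome 15, 89059734 to 89073567; 10.4 ± 2.11 against 6.92 ± 1.63 CPM), the bone sialoprotein gene Ibsp (10.1 ± 1.41 against 7.32 ± 1.03 CPM) and the kinase gene Ltk (0.65 ± 0.20 log2). None of these genes passed the adjustment over all genes.

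Oligodendrocyte genes fell as a list in this comparison by camera at the preset correlation. Their mean level per library differed by -0.68 log2 CPM, which did not pass (exact permutation p = 0.0878, adjusted over 13 cell type lists 0.285). Of those lists, microglial genes had the smallest p in that level test and were higher, by 0.34 log2 CPM (exact permutation p = 0.0155, adjusted 0.202). Part of this difference rests on NAc control replicate 3, the shallowest library, with a mean of 1.75 against 2.79 in the nearest control library. All 19 measured oligodendrocyte genes were lower in susceptible mice, with a median log2 fold change of -0.72, and the oligodendrocyte list fell by camera (adjusted p = 3.94e-13, and 0.806 with an estimated correlation). Its leading members were Ugt8a, needed for myelin galactolipids, at -0.68 ± 0.27, and the tetraspanin Tspan2 at -0.73 ± 0.29. The tight junction protein Cldn11 of myelin stood at -0.93 ± 0.41, and 0 of 19 passed when adjusted over the list alone, against 16 and 17 without NAc susceptible replicate 3 and NAc control replicate 7. Transcripts encoded by mitochondrial DNA also fell as a list (median -0.50, 12 of 12 lower; adjusted p = 9.14e-05, adjusted p = 0.806 with an estimated correlation), a call lost with marker components (median -0.13, adjusted p = 0.236). Astrocyte identity genes did not pass (median -0.19, 23 of 26 lower; adjusted p = 0.152), and with marker components their median was 0.13 (adjusted p = 0.00788, and 0.696 with an estimated correlation). Within that list Gfap, the filament protein of reactive astrocytes, stood at 0.67 ± 0.27 log2, and the acute-phase gene Lcn2 at 1.06 ± 0.53, with a susceptible mean of 3.98 CPM that became 2.43 CPM without NAc susceptible replicate 4. The pan-reactive list holding both had a median of -0.03 and a mean of 0.12 (adjusted p = 0.834), and neither gene passed when adjusted over the list alone. CREB-responsive genes did not pass either (adjusted p = 0.966), with a median of 0.03 and a mean of -0.02. The phosphodiesterase Pde4b stood at -0.64 ± 0.27, the immediate early gene Arc at -0.42 ± 0.26 and the granin Scg2 at -0.72 ± 0.44. Scg2 was at 0.13 with marker components, and its control mean of 12.2 CPM became 6.34 CPM without NAc control replicate 3. The CREB family list did not pass (median -0.04, adjusted p = 0.47).

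By edgeR 0 of 35943 genes passed in this comparison (smallest adjusted p = 1.00), and 1086 had an unadjusted p under 0.05, 528 higher and 558 lower. Unchanged genes alone would give about 1797 at that level in each NAc comparison. DESeq2 and limma-voom also called 0, with 1348 and 1335 genes at an unadjusted p under 0.05. That count was 1976, 598 and 1800 without NAc control replicates 5, 6 and 7 and 646 and 720 without NAc susceptible replicates 7 and 8. Of 39 lists 12 passed camera, 3 higher and 9 lower, and 0 passed with an estimated correlation or by fry (smallest adjusted p = 0.681).

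Resilient against control mice in the NAc address which astrocyte features go with keeping social behaviour after defeat. Dnaja1, a heat shock co-chaperone (ENSMUSG00000028410.13, chromosome 4, 40722150 to 40737149), stood at 14.2 ± 4.20 CPM in 7 resilient against 25.9 ± 7.45 CPM in 7 control libraries (-0.80 ± 0.21 log2). The carbonic anhydrase Car4 (chromosome 11, 84957786 to 84966044) was at 9.05 ± 1.29 against 13.5 ± 2.83 CPM. The aggrecan-cleaving protease Adamts4 (chromosome 1, 171250421 to 171260637) was at 15.4 ± 5.78 against 36.6 ± 21.6 CPM and Bcas1, a gene of myelinating oligodendrocytes (chromosome 2, 170346991 to 170427845), at 81.1 ± 17.5 against 120.5 ± 31.9 CPM. On the higher side stood the leucine-rich repeat gene Nyx (11.7 ± 4.24 against 6.50 ± 1.90 CPM), Ripply3 (0.79 ± 0.21 log2) and the chemosensory receptors Vmn1r234, Olfr292 and Olfr169, whose families carry the background cover. Creb1 stood at 53.8 ± 10.3 CPM, -0.21 ± 0.15 log2 from control, Crem at -0.03 ± 0.13 and Atf1 at -0.06 ± 0.11, and each turned positive with marker components (0.02, 0.12 and 0.03). No gene passed the adjustment over all genes.

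Oligodendrocyte, heat shock and astrocyte identity genes were lower as lists in the resilient libraries. Over only genes above background the median log2 fold change was itself -0.19, so part of such a fall was not particular to a list. All 19 oligodendrocyte members were lower (median -0.97; adjusted p = 3.21e-16 by camera, and 0.443 with an estimated correlation), and 18 passed when adjusted over the list alone. Of them 0 did without NAc control replicate 4 or 6 or NAc resilient replicate 3, 5 or 6. With the background percent as a covariate, chosen after the data were seen, 0 of them did (median -0.53). The heat shock and unfolded protein list fell (median -0.49, 28 of 31 lower; adjusted p = 1.42e-13, and 0.443 with an estimated correlation). The small heat shock protein Hspb1 stood at -1.01 ± 0.29, the chaperone Hsp90aa1 at -1.37 ± 0.42 and the reticulum chaperone Hspa5 at -0.97 ± 0.35. Of these 31, Dnaja1, Hspb1 and Hsp90aa1 passed when adjusted over the list alone, and single libraries left out gave 0 to 22, 0 without NAc control replicate 6 or NAc resilient replicate 4 and 22 without NAc resilient replicate 1. Astrocyte identity genes fell as well (median -0.53, 25 of 26 lower; adjusted p = 7.86e-08, and 0.443 with an estimated correlation), among them Aqp4 at -0.85 ± 0.34 and the deiodinase Dio2 at -0.70 ± 0.33, with 0 passing when adjusted over the list alone and 19 without NAc resilient replicate 1. The list no longer passed with the background covariate (median -0.10, adjusted p = 0.596) or with marker components (median -0.05, adjusted p = 0.246). The CREB family list passed with a small median (-0.08, 11 of 15 lower; adjusted p = 0.0423, and 0.454 with an estimated correlation), led by the coactivator Crebbp at -0.47 ± 0.18, and 0 members passed when adjusted over the list alone. CREB-responsive genes did not pass (median -0.05, adjusted p = 0.212; median 0.04 with the background covariate), with Pde4b at -0.62 ± 0.28, Arc at -0.58 ± 0.27 and the neurotrophin Bdnf at 0.24 ± 0.14. The background percent was 11.4 points higher in resilient than control libraries (exact permutation p = 0.0519), and the mean log2 CPM of the oligodendrocyte list was lower by a difference of -0.97 (exact permutation p = 0.0326, adjusted over 13 cell type lists 0.215). The oligodendrocyte precursor list differed by -0.23 and the pericyte and smooth muscle list by -0.34 (exact permutation p = 0.0478 and 0.0495, adjusted 0.215 for each). No other cell type list had an unadjusted p under 0.05.

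By edgeR 0 of 35943 genes passed for resilient against control mice (smallest adjusted p = 0.756), and 2206 had an unadjusted p under 0.05, 658 higher and 1548 lower. DESeq2 and limma-voom called 0, with 2792 and 3876 genes at that level. The count became 5620, 1394 and 1369 without NAc resilient replicates 1, 3 and 4 and 1159 without NAc control replicate 4. Of 39 lists 23 passed camera, 1 higher and 22 lower, and 0 passed with an estimated correlation or by fry (smallest adjusted p = 0.217).

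Susceptible against resilient mice in the NAc contrast the outcomes of the same stress. Car4 was at 12.9 ± 1.92 CPM in 8 susceptible against 9.05 ± 1.29 CPM in 7 resilient libraries (0.49 ± 0.13 log2), followed by the zinc finger gene Zfp830 at 0.85 ± 0.23, the acyltransferase Gpat2 at 0.47 ± 0.14 and the hydrolase Adprhl2 at 0.52 ± 0.16. On the lower side were the chemosensory receptors Olfr728, Vmn2r9 and Vmn1r215, and Glipr1l2 at -0.40 ± 0.12. Creb1 differed by -0.05 ± 0.15, Crem by -0.01 ± 0.12 and Atf1 by 0.02 ± 0.10, and each changed sign with some single library left out. The CREB family and CREB-responsive lists did not pass (medians 0.08 and 0.05, adjusted p = 0.118 and 0.114). Pan-reactive astrocyte genes rose as a list by camera (median 0.24; adjusted p = 0.0079, and 0.555 with an estimated correlation). Hspb1 at 0.91 ± 0.28 was the 1 member passing when adjusted over the list alone, with 0 passing in 9 of 22 fits with a single library left out and 3 without NAc resilient replicate 1. The serpin Serpina3n stood at 0.35 ± 0.19 and Gfap at 0.42 ± 0.26. Immediate early genes also rose as a list (median 0.16, 23 of 27 higher; adjusted p = 0.0017, and 0.555 with an estimated correlation), with Fos at 0.59 ± 0.24 and Jun at 0.75 ± 0.35, and 0 passing when adjusted over the list alone. With the background covariate neither list passed (medians 0.06 and 0.06, adjusted p = 0.330 and 0.491), nor did the pan-reactive list with marker components (median 0.13, adjusted p = 0.0554).

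By edgeR 0 of 35943 genes passed for susceptible against resilient mice (smallest adjusted p = 0.998), and 1042 had an unadjusted p under 0.05, 399 higher and 643 lower. DESeq2 and limma-voom called 0, with 1405 and 2994 at that level. The count became 2920 and 663 without NAc resilient replicates 1 and 7 and 550 without NAc susceptible replicate 4. All 19 of 39 lists that passed camera were higher in susceptible mice, and 0 passed with an estimated correlation or by fry (smallest adjusted p = 0.465). Over only genes above background the median log2 fold change was itself 0.13. With the background covariate 7 lists passed for resilient against control and 6 for susceptible against resilient mice, and 0 in either with an estimated correlation.

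**Figure D2:**
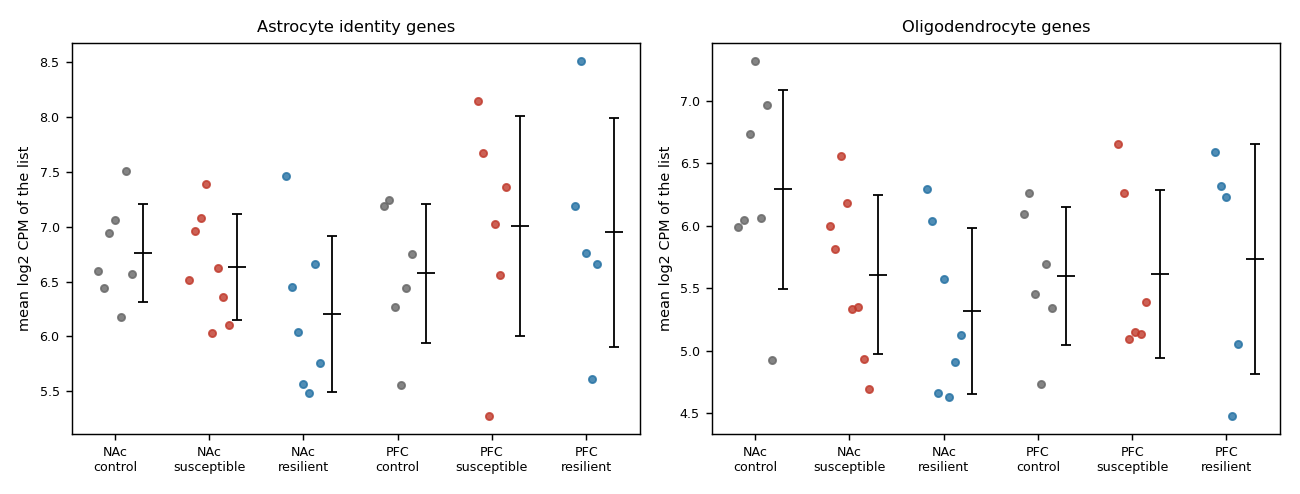
Mean log2 CPM of the astrocyte identity and oligodendrocyte lists in each library of the 6 groups; points are libraries and bars mean ± SD. The oligodendrocyte mean was 6.29 ± 0.79 in NAc control, 5.61 ± 0.64 in NAc susceptible and 5.32 ± 0.67 in NAc resilient libraries, and 5.60 to 5.73 in the PFC groups.

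The PFC libraries allow the same comparisons in a second region, with fewer mice and a wider spread. Acta2, the smooth muscle actin gene (ENSMUSG00000035783.9, chromosome 19, 34241090 to 34255590), stood at 29.5 ± 19.9 CPM in 6 susceptible against 13.5 ± 3.74 CPM in 6 control libraries (1.14 ± 0.31 log2; higher in 6 of 6 same-numbered pairs), and the tropomyosin Tpm2 at 12.6 ± 5.33 against 7.23 ± 2.49 CPM. The betaine and GABA transporter Slc6a12 (chromosome 6, 121343076 to 121365775) was at 33.9 ± 8.45 against 22.2 ± 3.62 CPM. Asparagine synthetase, Asns (chromosome 6, 7675169 to 7693254), was at 7.93 ± 2.75 against 14.1 ± 3.71 CPM, and the pentose phosphate enzyme Rpia at -0.42 ± 0.17 log2. In same-numbered pairs Tpm2 was higher in 6 of 6 and Slc6a12 in 5 of 6, and Asns and Rpia were lower in 6 of 6. Such signs follow in part from picking genes by their p. None passed the adjustment over all genes.

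Astrocyte, vessel wall and red blood cell lists passed camera with higher values in PFC susceptible than control mice. Over only genes above background the median log2 fold change was itself 0.11, so part of such a rise was not particular to a list. All 26 astrocyte identity genes were higher (median 0.69; adjusted p = 8.84e-12 by camera, and 0.392 with an estimated correlation), led by Gfap at 0.76 ± 0.32 and Aldh1l1 at 0.42 ± 0.24, each higher in 5 of 6 same-numbered pairs, with 0 passing when adjusted over the list alone. The pericyte and smooth muscle list rose (median 0.41, 13 of 13 higher; adjusted p = 3.73e-09, and 0.278 with an estimated correlation), with Acta2 passing when adjusted over the list alone and the smooth muscle genes Tagln at 0.64 ± 0.26 and Myh11 at 0.36 ± 0.17 not passing. Haemoglobin genes rose as a list (median 1.29, 4 of 5 higher; adjusted p = 0.00181, and 0.392 with an estimated correlation), with Hba-a1 at 2.30 ± 0.81 and Hba-a2 at 2.05 ± 0.77 passing when adjusted over the list alone, although they were higher in only 3 and 4 of 6 same-numbered pairs. No haemoglobin gene passed so without PFC susceptible replicate 1, 2 or 4 (without the last, Hba-a1 was at 1.23 log2 and its susceptible mean at 3.31 instead of 6.86 CPM, and that of Hba-a2 at 2.91 instead of 4.58 CPM) or PFC control replicate 3, 4, 5 or 6, and Acta2 did not pass without PFC susceptible replicate 1 or PFC control replicate 3, 4 or 5. The haemoglobin list no longer passed with the replicate number as a block (median 1.01, adjusted p = 0.0900; 0 members passing over the list alone), the background covariate (1.34, 0.107) or marker components (1.38, 0.129). Mean levels of the astrocyte, pericyte and smooth muscle, and haemoglobin lists differed by 0.43, 0.41 and 0.32 log2 CPM between these groups (exact permutation p = 0.392, 0.253 and 0.719). Within the same-numbered pairs, a test chosen after the data were seen, these lists were higher in 5, 6 and 4 of 6 pairs (exact p = 0.25, 0.03125 and 0.719, of which 0.03125 is the smallest that 6 pairs allow; adjusted over 13 lists 0.542, 0.406 and 0.846). By edgeR 0 of 32167 genes passed (smallest adjusted p = 1.00), and 155 had an unadjusted p under 0.05, 114 higher and 41 lower. Unchanged genes alone would give about 1608 at that level in each PFC comparison, so low p-values were far rarer than under chance. With the replicate block 819 genes reached that level, and with the background covariate 1058. DESeq2 and limma-voom called 0, with 212 and 1733 at that level. The count was 266, 85 and 71 without PFC control replicates 2, 3 and 4, 502 and 521 without PFC susceptible replicates 1 and 3, and 247 without PFC resilient replicate 2. Of 40 lists 23 passed camera, 22 higher and 1 lower, and 0 with an estimated correlation or by fry (smallest adjusted p = 0.94).

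In PFC resilient against control mice, Hba-a1 was at 7.27 ± 9.04 CPM in 5 resilient against 1.54 ± 0.871 CPM in 6 control libraries (2.31 ± 0.84 log2), and at 3.36 CPM without PFC resilient replicate 1. Hbb-bs stood at 1.89 ± 0.72 and Hba-a2 at 2.05 ± 0.80, and the haemoglobin list rose (median 1.89; adjusted p = 1.22e-05, and 0.591 with an estimated correlation). These 3 members passed when adjusted over the list alone, and 0 did without PFC resilient replicate 1 or 2 or PFC control replicate 4 or 5, or with the replicate block. Without PFC resilient replicate 1 the resilient mean of Hba-a2 was 3.12 instead of 4.82 CPM. The mean level of the list differed by 1.03 log2 CPM (exact permutation p = 0.136), and within same-numbered pairs it was higher in 4 of 5 (exact p = 0.125, where 5 pairs allow 0.0625 at the smallest). Of the cell type lists, only striatal projection neuron genes had an unadjusted level p under 0.05 (-0.35 log2 CPM, exact permutation p = 0.0173, adjusted 0.225). Their resilient levels ran from 3.12 in replicate 3, among the shallowest libraries, to 3.95 in replicate 4, against a control mean of 3.97. Astrocyte identity genes were higher in 5 of 5 pairs and striatal and ependymal genes in 0 of 5 (exact p = 0.0625, adjusted 0.271 for each). The zinc finger gene Zfp791 was at 45.0 ± 52.9 against 14.4 ± 3.53 CPM, and at 21.9 CPM without PFC resilient replicate 3. The mitochondrial mt-Atp8, which overlaps mt-Atp6, was at 7.88 ± 11.8 against 0.727 ± 0.806 CPM, at 2.89 CPM without PFC resilient replicate 3 and at 0.425 CPM in controls without replicate 1. It was higher in 2 and lower in 3 of 5 same-numbered pairs, and its log2 fold change was -0.03 with marker components. Lower values were those of the peroxisome gene Pex11g at -0.99 ± 0.36, the mast cell protease Cma1 at -1.39 ± 0.52 (resilient mean 0.909 CPM, 0.519 without PFC resilient replicate 4) and the neurofilament Nefh (6.06 ± 1.48 against 9.89 ± 2.78 CPM). No gene passed over all genes by edgeR (0 of 32167, smallest adjusted p = 1.00), and 192 had an unadjusted p under 0.05, 131 higher and 61 lower. DESeq2 and limma-voom called 0, with 308 and 1522 at that level. The count was 289, 365, 117, 99, 113 and 126 without PFC control replicates 1, 2, 3, 4, 5 and 6, and 113, 1090 and 332 without PFC resilient replicates 3, 4 and 5. Of 40 lists 21 passed camera, 18 higher and 3 lower, and 0 with an estimated correlation or by fry (smallest adjusted p = 0.903). Over only genes above background the median log2 fold change was itself 0.11.

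In PFC susceptible against resilient mice, Acta2 stood at 29.5 ± 19.9 against 12.3 ± 3.16 CPM (1.26 ± 0.34 log2, n = 6 and 5), Myh11 (chromosome 16, 14194535 to 14291372) at 101 ± 16.7 against 68.4 ± 16.4 CPM, Tpm2 at 0.89 ± 0.29 and Tagln at 0.85 ± 0.29. In same-numbered pairs Tpm2 was higher in 4 of 5 and Acta2, Myh11 and Tagln in 5 of 5, signs that follow in part from picking genes by their p. Acta2, Myh11 and Tagln passed when adjusted over the pericyte and smooth muscle list alone, and the list passed camera (adjusted p = 0.00357, and 0.969 with an estimated correlation) with a median of only 0.04. Its mean level differed by 0.27 log2 CPM (exact permutation p = 0.548) and by 0.29 within same-numbered pairs, higher in 4 of 5 (exact p = 0.1875, where 5 pairs allow 0.0625 at the smallest), and without the 3 shallowest libraries it did not pass (median -0.04, adjusted p = 0.142). With a single library left out, 0 to 3 members passed over the list alone, 0 without PFC resilient replicate 3 and 1 without PFC resilient replicate 1 or 2 or PFC susceptible replicate 1 or 3, and 2 with the replicate block. The immune gene H2-Q6 at 1.21 ± 0.41, from a family of close copies, was also higher, and Zc4h2 at -0.76 ± 0.27 and the neurite factor Ndnf at -0.64 ± 0.25 were lower, none passing over all genes. By edgeR 0 of 32167 genes passed (smallest adjusted p = 1.00), and 184 had an unadjusted p under 0.05, 109 higher and 75 lower. DESeq2 and limma-voom called 0, with 261 and 2178 at that level. The count was 376 and 605 without PFC resilient replicates 2 and 4 and 778 without PFC susceptible replicate 1. Of 40 lists 4 passed camera, 3 higher and 1 lower, and 0 with an estimated correlation or by fry (smallest adjusted p = 0.994); 1 passed without the 3 shallowest libraries.

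Control mice of the 2 regions show how far the sorted cells differ by region without stress. Crym, which encodes mu-crystallin, a cytosolic thyroid hormone-binding protein (ENSMUSG00000030905.5, mm10 chromosome 7, 120186380 to 120202111), was higher in NAc, at 121 ± 69.0 CPM in 7 NAc control against 17.3 ± 4.92 CPM in 6 PFC control libraries. Its log2 fold change of 2.81 ± 0.41 was the 1 difference past the adjustment over all genes (adjusted p = 0.00201). Next on the NAc side, without passing, were the Wnt receptor Fzd5 (chromosome 1, 64730558 to 64737751; 15.8 ± 3.79 against 5.33 ± 1.2 CPM) and the complement component C4b (chromosome 17, 34728380 to 34743882; 44.8 ± 12.9 against 16.1 ± 2.99 CPM). They were followed by the forebrain transcription factor Six3 at 1.13 ± 0.29 log2 with its antisense gene Six3os1 at 1.21 ± 0.29, and by Bcas1 at 0.66 ± 0.15. On the PFC side, also without passing, the vesicular glutamate transporter Slc17a7 (chromosome 7, 45163949 to 45176142) was at 9.52 ± 2.08 CPM in NAc against 98.0 ± 119 CPM in PFC, the latter 53.6 CPM without PFC control replicate 2. It was joined by the cortical transcription factor Neurod2 at -2.57 ± 0.54, the postsynaptic protein gene Nrgn at -3.19 ± 0.68 and the Nogo receptor Rtn4r at -1.66 ± 0.38. Without that library the PFC means of these 3 genes were 5.83 instead of 9.24, 38.9 instead of 71.7 and 27.6 instead of 41.7 CPM.

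Neuronal genes were lower as lists in NAc than PFC. All 18 pan-neuronal genes were lower in NAc than PFC control libraries (median -1.03; adjusted p = 7.95e-20 by camera, and 0.174 with an estimated correlation), and 15 passed when adjusted over the list alone, against 1 without PFC control replicate 2. The mean level of the list differed by -0.94 log2 CPM, which did not pass (exact permutation p = 0.0105, adjusted over 13 lists 0.0682). Stmn2 stood at -0.80 ± 0.21 and the neurofilaments Nefm at -0.85 ± 0.23 and Nefl at -2.06 ± 0.56, the last with a PFC mean of 10.9 CPM that became 6.41 CPM without that library. Cortical excitatory neuron genes fell likewise (median -0.82, 13 of 17 lower, 10 passing when adjusted over the list alone; adjusted p = 7.2e-15, and 0.0892 with an estimated correlation). Neurod6 stood at -2.20 ± 0.53 and the vesicular zinc transporter Slc30a3 at -1.28 ± 0.32, and the mean log2 CPM of the list differed by -0.93 (exact permutation p = 0.000583; adjusted over 13 lists 0.00758). Striatal projection neuron genes were higher in NAc as a list (median 0.14, 11 of 18 higher; adjusted p = 0.000944, and 0.353 with an estimated correlation), with the opioid precursor Penk at 1.73 ± 0.59 and the G-protein regulator Rgs9 at 0.57 ± 0.18 passing when adjusted over the list alone, although 0 members passed in 23 of 39 fits with a single library left out. The NAc mean of Penk was 17.9 CPM, and 9.65 CPM without NAc control replicate 3. The striatal list did not pass with marker components (median 0.10, adjusted p = 0.691) or without the 3 shallowest libraries (median 0.11, adjusted p = 0.109). Without control replicates 1 and 2 of both regions, a choice made after the data were seen, the medians of the pan-neuronal, cortical and striatal lists were -0.31, -0.36 and 0.07.

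Oligodendrocyte genes were higher in NAc (median 0.77, 19 of 19 higher; adjusted p = 5.78e-15, and 0.311 with an estimated correlation), with the myelin genes Mobp at 1.15 ± 0.45 and Mbp at 0.99 ± 0.39 and 0 passing when adjusted over the list alone, against 14 and 9 without NAc control replicate 7 and PFC control replicate 2. Without control replicates 1 and 2 of both regions the median was 1.28. Immediate early genes were lower in NAc (median -0.54, 25 of 27 lower, 7 passing when adjusted over the list alone; adjusted p = 2.31e-07, and 0.321 with an estimated correlation), led by Egr1 at -2.61 ± 0.63, Egr3 at -2.47 ± 0.65 and Arc at -2.08 ± 0.62. Of this list 0 passed without PFC control replicate 2, where the PFC means of these 3 genes were 20.0, 14.3 and 17.3 instead of 37.2, 27.1 and 33.9 CPM. CREB-responsive genes were lower as well (median -0.26, 24 of 30 lower; adjusted p = 3.26e-05, and 0.510 with an estimated correlation). That list shares Arc with the immediate early list, so the 2 results are not independent. Microglial genes were lower too (median -0.36, 18 of 21 lower, 3 passing when adjusted over the list alone; adjusted p = 2.1e-07, and 0.245 with an estimated correlation), such as the complement genes C1qb at -0.84 ± 0.28 and C1qc at -1.03 ± 0.36, with 0 members passing over the list alone in 8 of 39 fits with a single library left out. With marker components neither the immediate early list (median 0.03, adjusted p = 0.478) nor the microglial list (median -0.09, adjusted p = 0.136) passed. The list of regional telencephalic genes did not pass as a whole (adjusted p = 0.644), since its members went both ways. Crym and Six3 were higher in NAc, and Zic5 at -1.07 ± 0.32 and the cortical factor Tbr1 at -1.11 ± 0.36 lower, each passing when adjusted over the list alone, although Tbr1 was at 0.07 with marker components and the number passing was 2 to 7 with single libraries left out.

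By edgeR 1 of 38171 genes passed between the regions and 1924 had an unadjusted p under 0.05, 414 higher and 1510 lower. DESeq2 called 129 and limma-voom 16. In edgeR with the background covariate 297 genes passed, 84 higher and 213 lower, and Fzd5 (1.67 ± 0.29), C4b (1.55 ± 0.31), Slc17a7 (-2.40 ± 0.43) and Neurod2 (-1.95 ± 0.37) were among them. Crym passed in 55 of 56 alternative fits and not with 2 cell type marker components (2.34 ± 0.49, adjusted p = 0.415). Its log2 fold changes over all fits were 2.25 to 3.20, with adjusted p of 1.13e-10 to 0.415. The fits without NAc resilient replicate 1 and without PFC susceptible replicate 1 called 3 genes each, and the count at an unadjusted p under 0.05 was 995 without PFC control replicate 2. Of 40 lists 13 passed camera, 5 higher and 8 lower, and 0 with an estimated correlation or by fry (smallest adjusted p = 0.124).

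**Figure D3:**
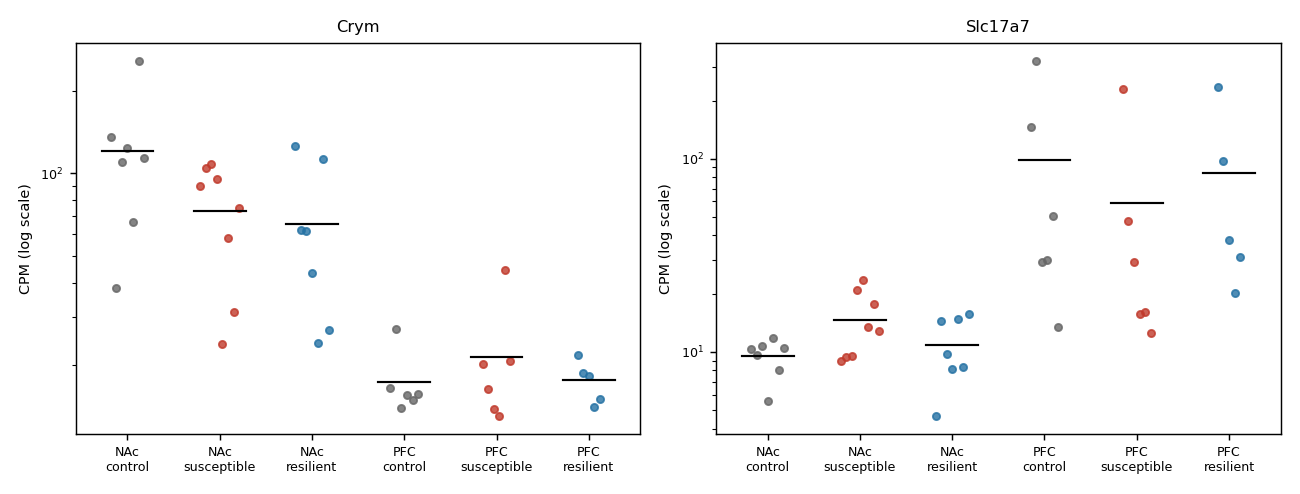
CPM of Crym and Slc17a7 in each library of the 6 groups on log axes; points are libraries and lines group means. Crym averaged 121 CPM in NAc control and 17.3 CPM in PFC control libraries, and Slc17a7 ranged from 13.4 to 320 CPM in PFC control libraries.

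Whether stress acted differently in the 2 regions was tested as the difference between the NAc and PFC effects. For the susceptible effect, Acta2 stood first at -1.39 ± 0.34 log2, with 11.7 ± 2.86 and 14.2 ± 2.74 CPM in NAc susceptible and control libraries and 31.0 ± 21.4 and 14.3 ± 4.16 CPM in PFC. Then came the kinesin Kif22 at 0.70 ± 0.22, Asns at 0.86 ± 0.28, the cytochrome Cyp4x1 at 0.76 ± 0.25 and Trp53i13 at -0.80 ± 0.28. For the resilient effect the leading genes were Ripply3 at 1.45 ± 0.38, the interleukin receptor Il10ra at 1.13 ± 0.33, the myosin Myh14 at -0.76 ± 0.23, the splicing factor Plrg1 at -0.96 ± 0.30 and the antisense gene Znrd1as at 1.00 ± 0.32. None of these passed by edgeR, and Acta2 was the 1 gene that limma-voom called (-1.16 ± 0.20, adjusted p = 0.0256). By edgeR 0 of 38171 genes passed in either (smallest adjusted p = 1.00 and 0.849), and 528 and 1318 had an unadjusted p under 0.05. DESeq2 called 0 in both, with 782 and 1941 at that level, and limma-voom 1 and 0, with 1766 and 2203. For the susceptible effect the count was 1483, 809 and 325 without PFC susceptible replicates 3, 1 and 2 and 1046 without PFC control replicate 2. For the resilient effect it was 530, 4798 and 2263 without PFC resilient replicates 2, 4 and 5, 3500 and 733 without PFC control replicates 2 and 4, 2907 without NAc resilient replicate 1 and 802 without NAc control replicate 6.

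Fold changes of the susceptible and resilient mice against the same controls were correlated across genes, which are not independent replicates. In NAc Pearson's r was 0.835 and Spearman's rho 0.803 over 27528 genes. Simulated unchanged groups against those controls gave an r of 0.575, and controls split between the comparisons gave 0.149 on average. The observed covariance was 0.0986 against 0.0268 simulated, 80.2% of genes moved the same way against 69.5% simulated, and 15 of 100 relabellings of the libraries gave an r as large. In PFC r was 0.437 and rho 0.485 over 26992 genes, against 0.449 simulated for r and 0.0569 with split controls, and 52 of 100 relabellings gave an r as large. Neither the simulation nor those relabellings kept same-numbered PFC libraries together, and with labels exchanged only within a replicate number, a choice made after the data were seen, 58 of 100 gave an r as large, with a mean of 0.503. The covariance was 0.0455 against 0.0670 simulated and 0.0537 within numbers. No gene was called in both comparisons of either region. Between the regions, which share no libraries, the susceptible effects had an r of -0.27 (permutation p = 0.299) and a rho of -0.30 (permutation p = 0.311) and the resilient effects an r of -0.41 (permutation p = 0.136) and a rho of -0.46 (permutation p = 0.125), over 27294 genes and 1000 relabellings, which did not keep same-numbered libraries together.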

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

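The tests of X-linked pseudogenes, of the background covariate for neuronal genes and of striatal against cortical genes were chosen after their results were seen, and the background measure itself was devised after the data were examined.

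Signal outside the comparisons appeared in 1479 chemosensory receptor genes, whose cover had a median of 58.2% of an even cover over the 39 libraries. Reads shared between receptor paralogs are argued against, since 60 single-copy genes of other organs had a median FPKM 1.54 times that of the receptor genes. Genomic DNA in the libraries may account for it: X-linked processed pseudogenes, of which a male cell holds a single chromosome copy, had a median FPKM 0.506 times that of autosomal ones. Unspliced or read-through transcription was not tested, and no biological explanation was tested.

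Oligodendrocyte genes were lower in NAc resilient than control libraries, with a median of -0.97, and their mean level was 0.29 log2 CPM higher in susceptible than resilient libraries, which did not pass (exact permutation p = 0.397). Whether the larger background of the resilient libraries accounts for it cannot be told apart from a loss of oligodendrocyte transcripts, since the oligodendrocyte minus astrocyte mean differed by -0.42 with an exact permutation p of 0.213, while in susceptible libraries, whose background was 2.83 points above control (exact permutation p = 0.535), it differed by -0.56 (exact permutation p = 0.0499, unadjusted) and the oligodendrocyte mean itself by -0.68, which did not pass (exact permutation p = 0.0878, adjusted over 13 lists 0.285). For less oligodendrocyte material carried through the sort, the test was whether the members move together. All 19 did, with an SD of 0.295 between their fold changes against a median standard error of 0.391. This cannot decide the question, because the list was flagged for its lower members. Background or a change of oligodendrocytes would also move the members together. Of 100 splits of the 14 libraries, the real one counted, 4 gave as many members passing when adjusted over the list alone (real 18, highest other 19). That is under the 5% level set for this test, but it does not exclude chance. This was 1 of 13 cell type lists, its level test had an adjusted p of 0.215, and 0 members passed in 5 of 22 fits with a single library left out. A change of oligodendrocytes with resilience, or with defeat stress whatever its outcome, stays open as untested.

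Neuronal genes were higher in PFC than NAc control libraries, with a median of -1.03 for NAc against PFC. A lower background in PFC as the whole cause is argued against, because with the background covariate the pan-neuronal list passed with an estimated correlation (adjusted p = 0.0301, median -0.72). The libraries with the lowest sample numbers could carry much of it, since without control replicates 1 and 2 of both regions the median was -0.31. For neurons of the punched tissue carried through the sort, the striatal median exceeded the cortical one by 0.96. Most of this is the cortical median of -0.82, which is part of the flagged pattern itself, so the test cannot decide. The striatal median was 0.14, and the mean level of that list differed by 0.20 log2 CPM (exact permutation p = 0.171, adjusted over 13 lists 0.318). Without those replicates the striatal median exceeded the cortical one by 0.43, less than this explanation was held to need. A difference between the regions in the sorted astrocytes themselves stays open as untested.

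Many lists passed camera for a difference of the stress effect between the regions, within the range of 4 to 23 of the 7 comparisons of 2 groups. For the susceptible effect 20 of 40 lists passed, 1 higher and 19 lower in NAc, and for the resilient effect 22 passed, 2 higher and 20 lower. Over only genes above background the medians of these 2 effects were themselves -0.15 and -0.26. With an estimated correlation 0 passed in either, with smallest adjusted p-values of 0.527 and 0.361.

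Single libraries stood apart from their group in 12 of 138 tests of levels, where chance alone is held to pick about 1 in 20. In NAc control replicate 3, the shallowest library, the mean log2 CPM of microglial genes was 1.75 against 2.79 in the nearest library, and that of vascular and leptomeningeal genes 2.00 against 3.43. In NAc susceptible replicate 4 endothelial genes averaged 5.13 against 4.71. NAc resilient replicate 1 had 1.77% mitochondrial counts against 1.02% and 1491 CPM of Slc1a3 against 724. PFC susceptible replicate 1 had a pan-neuronal mean of 7.59 against 6.14 and a vascular and leptomeningeal mean of 4.85 against 3.69. Aldh1l1 was at 109 CPM in PFC susceptible replicate 3 against 152, and in PFC resilient replicate 2 Aqp4 was at 430 CPM against 127 and Slc1a3 at 2385 against 906. Creb1 was at 49.4 CPM in PFC resilient replicate 4 against 56.1, and Atf1 at 23.1 CPM in PFC resilient replicate 3 against 32.1.

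Counts of genes at an unadjusted p under 0.05 were set beside splits of the same libraries, each number of splits counting the real one, and chance was not excluded for any stress comparison. In NAc, 27 of 100 splits gave as many genes for susceptible against control mice (real 1086, highest other 4401), 26 of 100 for resilient against control (2206 and 9792) and 36 of 100 for susceptible against resilient (1042 and 8317). In PFC it was 62 of 100 (155 and 13120), 42 of 100 (192 and 16928) and 86 of 100 (184 and 9772). Among PFC splits that part as many same-numbered pairs, it was 16 of 32 with a highest other of 341, 6 of 32 with 347 and 25 of 32 with 1051, so every higher count came from a split that keeps more pairs together. For the interactions it was 34 of 60 (528 and 15569) and 21 of 60 (1318 and 17705). Some other splits also called many genes, up to 3421 for NAc susceptible against resilient mice, 4157 and 12493 for the PFC comparisons with controls and 9046 and 12746 for the interactions, which points to a structure of the libraries other than the conditions. Between the regions in controls, 2 of 60 splits called as many genes as the real one (1, highest other 2). With the background covariate, chosen after the data were examined, it was 1 of 60 (297, highest other 245). Few splits reached the real counts, but chance is not excluded for either. A split other than the real one called 2 genes, and with the covariate such a split called 245.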

How the results depend on the processing

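The tests with the background covariate, with only genes above background, with both and without the 3 shallowest libraries were chosen after the data were examined, and the causes of the changes below were not tested.

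By edgeR 0 genes were called in each of the 6 stress comparisons within a region, in the 16 other settings of each, DESeq2 and limma-voom included, and with any single library left out. Counting genes at an unadjusted p under 0.05 with a fold above 1.3 instead gave 740, 1522 and 629 genes in NAc for susceptible against control, resilient against control and susceptible against resilient mice, 151, 192 and 182 in PFC in the same order, 1689 between the regions, and 520 and 1309 for the susceptible and resilient interactions. At an unadjusted p under 0.05 alone, leaving out single libraries gave 598 to 1976, 1159 to 5620 and 550 to 2920 genes in the NAc comparisons and 71 to 521, 99 to 1090 and 145 to 778 in the PFC ones. Limma-voom called 1 gene for the susceptible interaction. At the joint depth, spread and group sizes of PFC, and with genes drawn independently, the simulated susceptible comparison recovered 1.49% of 1.5-fold and 22.4% of 2-fold changes.

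The number of genes called between the regions, 1 in edgeR as reported, moved with the setting. It was 297 with the background covariate, 2 with only genes above background, 352 with both, 0 with marker components of other cell types, 129 by DESeq2, 250 with 2 surrogate variables, 16 by limma-voom, 3 with consecutive sample numbers as pairs and 3 with only the 13 control libraries. It ranged from 1 to 3 with single libraries left out. Of the 129, 250 and 16 genes, 119, 186 and 15 were among the 297, and 228 of the 352 were.

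Counts of gene lists moved with the set test. Camera with an estimated correlation and fry called 0 lists in all 9 comparisons, while 2 lists, pan-neuronal and cortical excitatory neuron genes, passed between the regions with both an estimated correlation and the background covariate (adjusted p = 0.0301 for each). With the background covariate camera called 7 lists for NAc resilient against control, 6 for NAc susceptible against resilient and 20 between the regions. With marker components it called 5 for NAc resilient against control, 14, 10 and 15 in PFC for susceptible against control, resilient against control and susceptible against resilient, and 12 and 7 for the susceptible and resilient interactions. Without the 3 shallowest libraries 1 list passed for PFC susceptible against resilient mice. The correlation of susceptible and resilient effects fell to 0.149 in NAc and 0.0569 in PFC with split controls, where fewer libraries enter each comparison.

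With the replicate block 0 genes were called in every stress comparison and 1 between the regions, as without it. The block changed the camera call of 24 lists over the 9 comparisons, 19 gained and 5 lost, of which 8 were in the PFC conditions, and 0 lists passed with an estimated correlation, nor with marker components or without the 3 shallowest libraries. Over the list alone the block passed 13 heat shock genes in NAc resilient against control and 17 oligodendrocyte and 5 striatal genes between the regions, against 3, 0 and 2 without it, and 0 instead of 1 pan-reactive gene in NAc susceptible against resilient. In NAc susceptible against resilient mice the CREB family and CREB-responsive lists were among those gained (adjusted p = 0.0482 for each). Same-numbered NAc libraries correlated from -0.251 to 0.514 for control with susceptible, -0.314 to 0.433 for control with resilient and -0.435 to 0.351 for susceptible with resilient libraries, and 2, 0 and 0 of 7 correlated best with their own number. Over 16 pairs of consecutive sample numbers the mean correlation was 0.140 (permutation p = 0.0859).

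Named genes gave 191 results, each a gene in 1 comparison, with 7604 values under the alternatives. Of these, 7476 kept their direction and side of the threshold, 79 newly passed (all between the regions apart from Acta2 in the susceptible interaction by limma-voom), 1 no longer passed and 48, from 15 results, changed sign, none of them among called genes. For NAc susceptible against control, Crem was 0.0276 with marker components, 0.0206 on FPKM and 0.0468 with surrogate variables. With single libraries left out it ranged from -0.103 to 0.0236, above 0 without susceptible replicate 7 or control replicate 6. Atf1 was 0.0537 with marker components, 0.0128 on FPKM, 0.0314 with surrogate variables, 0.000913 by limma-voom and 0.00229 without the 3 shallowest libraries. With single libraries left out it ranged from -0.0680 to 0.00229, above 0 without control replicate 3, and Scg2 was 0.125 with marker components. For NAc resilient against control, Creb1 was 0.0231 with marker components and 0.0735 with surrogate variables. Crem was 0.0623 with the background covariate, 0.122 with marker components, 0.0407 on FPKM, 0.0173 with the sample number, 0.117 with surrogate variables and 0.00396 by limma-voom. With single libraries left out it ranged from -0.0744 to 0.0335, above 0 without resilient replicate 5 or control replicate 6. Atf1 was 0.0509 with the background covariate, 0.0504 with genes above background as well, 0.0294 with marker components, 0.00714 on FPKM, 0.0335 with surrogate variables and 0.00278 by limma-voom, and Acsbg1 was 0.00775 with surrogate variables.

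For NAc susceptible against resilient, Creb1 ranged from -0.117 to 0.0211 with single libraries left out, above 0 without resilient replicate 1. Crem was 0.0294 with the replicate block. With single libraries left out it ranged from -0.0720 to 0.0453, above 0 without resilient replicates 1 or 2 or susceptible replicates 5, 6, 7 or 8. Atf1 was -0.0653 with the background covariate, -0.0671 with genes above background as well, -0.00208 with surrogate variables, -0.00187 by limma-voom. With single libraries left out it ranged from -0.0260, without resilient replicate 5, to 0.0553. In PFC resilient against control, marker components gave -0.0341 for mt-Atp8, -0.337 for mt-Co2 and -0.00355 for mt-Co3, and limma-voom gave -0.0880 for mt-Atp6 and -0.0307 for mt-Co3. Tbr1 between the regions was 0.0718 with marker components.

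Medians of lists changed sign as well. With marker components they were 0.129 for astrocyte identity (adjusted p = 0.00788), 0.0205 for pan-reactive astrocyte and 0.0537 for CREB family genes in NAc susceptible against control, 0.0486 for CREB-responsive genes in NAc resilient against control, -0.179 for mitochondrially encoded genes in PFC resilient against control (adjusted p = 0.0359) and 0.0319 for immediate early genes between the regions. With the background covariate CREB-responsive genes in NAc resilient against control were at 0.0395. Without the 3 shallowest libraries the pericyte and smooth muscle list in PFC susceptible against resilient mice was at -0.0429.

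The median of all genes shifted by more than 0.1 with only genes above background, by -0.20 and 0.11 for NAc resilient against control and susceptible against resilient, 0.12 and 0.12 for PFC susceptible and resilient against control, and -0.21 and -0.33 for the interactions. When the background covariate was added it shifted by -0.11 for the susceptible interaction.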

Other observations

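The lists described here were picked after their results were seen, and the tests with the background covariate were chosen after the data were examined.

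In the NAc, ribosomal protein genes fell as a list in resilient against control mice (median -0.54, 47 of 47 lower; adjusted p = 1.66e-18 by camera, and 0.443 with an estimated correlation), and 0 members passed when adjusted over the list alone, against 43 without NAc resilient replicate 1. Rpl15 stood at -0.86 ± 0.31 and Rps19 at -0.49 ± 0.19. With the background covariate their median was -0.14 (adjusted p = 0.00104, and 0.873 with an estimated correlation). Genes of cholesterol synthesis, a pathway by which astrocytes supply neurons with sterols, rose as a list in susceptible against resilient mice (median 0.32, 24 of 24 higher; adjusted p = 7e-09, and 0.555 with an estimated correlation), and 0 members passed when adjusted over the list alone, against 16 without that library. Hmgcs1 stood at 0.60 ± 0.31 and Fdps at 0.43 ± 0.19. With the background covariate the list did not pass (median 0.08, adjusted p = 0.141).

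In the PFC, transcripts of the mitochondrial genome rose as a list in resilient against control mice (median 0.80, 13 of 13 higher; adjusted p = 2.57e-08, and 0.591 with an estimated correlation), with the ATPase subunit mt-Atp6 at 2.92 ± 1.08 and the oxidase subunit mt-Co3 at 2.62 ± 1.00 and 0 passing when adjusted over the list alone, against 3 without PFC control replicate 1 or PFC resilient replicate 4 or 5. Without PFC resilient replicate 3 the resilient means of these 2 genes were 9.55 and 4.69 instead of 23.5 and 15.4 CPM, and without PFC control replicate 1 the control means were 2.03 and 1.43 instead of 3.18 and 2.50 CPM. Mitochondrial counts made up 2.09 ± 1.35% of resilient and 1.19 ± 0.712% of control libraries (exact permutation p = 0.199), of which mt-Atp6 and mt-Co3 carried little. Each of these 2 genes was higher in 3 of 5 same-numbered pairs. By limma-voom they stood at -0.09 and -0.03, and with marker components of other cell types the list's median was -0.18 (adjusted p = 0.0359, and 0.865 with an estimated correlation). Microglial genes fell as a list in the same mice (median -0.30, 17 of 20 lower; adjusted p = 0.000143, and 0.591 with an estimated correlation), among them the receptor Trem2 at -0.69 ± 0.32 and the lectin Siglech at -0.57 ± 0.35, but not with marker components (median -0.06, adjusted p = 0.542). Interferon response genes rose as a list in susceptible against control mice (median 0.19, 23 of 28 higher; adjusted p = 0.000257, and 0.143 with an estimated correlation), with the transcription factors Stat2 at 0.42 ± 0.21 and Irf1 at 0.48 ± 0.27. In neither list did a member pass when adjusted over the list alone.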
